A study of Rattus norvegicus with 6 samples.

How the data were processed

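RNA sequencing of dorsal root ganglia from 6 libraries, 3 SNI and 3 sham, was analysed from the deposited tables. Per the labels' protocols, total RNA was taken from frozen ganglia and made into Illumina libraries. The labels name both Trizol and a mirVana kit for the extraction and both a TruSeq and a NEBNext Ultra kit for the libraries, so the preparation used is uncertain. The aligner, the counting tool, the genome build, the annotation and the test behind the authors' gene lists are not given in the sources used here, nor is whether strand was recorded. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart.

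Per the file headers, the authors deposited TPM for each library for 1637 genes, a table of the average TPM and average read count of each group for 18696 genes, and lists of higher (699) and lower genes with KEGG pathway names. TPM corrects for gene length and scales each library to the same total, so that it keeps no depth. The TPM columns per library summed to between 25.8% and 27.1% of that total, as the deposited table held part of the genes. The average TPM columns in the authors' table summed to just under it. As deposited by the authors, the read counts are estimated counts averaged over the libraries of a group, with no counter named and no normalization given. They were whole when multiplied by 3 for 65.4% of genes in sham and 64.8% in SNI (tolerance 0.001). They summed to 18.590 M in sham and 18.591 M in SNI. Whether they were scaled to a common total is not known, so they may not give the depth of a group, and they do not give that of a library. All genes in the group-average table were above 0 in both averages. The columns named control were taken as the sham group, the other group in the labels. In 1628 genes of the per-library table the averages over a group's libraries were compared with the deposited averages, and they differed by less than the tolerance of 0.001 TPM.

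The plan made before the data were examined allowed for counts of all genes or for normalized values. As the values per library were TPM, the planned test for normalized values was used, and it ran within the per-library table. Genes with a mean of at least 1 TPM over the 6 libraries were kept (1596 genes; 41 were left out). The values were transformed as log2(TPM + 1) and compared with limma 3.58.1 (R 4.3.3), with an intensity trend, group as the only term and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The ratios of group averages used the same pseudocount of 1 and have no test. A permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so no single gene was tested that way.

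The 37 gene lists were fixed before the data were examined. Of their 861 members, 833 were matched to gene IDs of the files, 7 of them by the current symbol in a RefSeq gene table of the GRCr8 assembly. That table held 17448 of the 18729 gene IDs in the files and was used for names alone. No coordinates are given because the build of the files is not known. The 21 lists with at least 5 tested members were tested with camera with a preset correlation of 0.01. Camera compares a list with the other genes of the per-library table, which is itself a selection. As that table holds few members of most lists, 2 descriptions were added after seeing the data. Fisher's exact test (two-sided, adjusted over 36 lists) compared the share of a list's members found in the authors' higher or lower list with that of other genes. It treats genes as independent, though genes of a list can move together. Its background was the 16596 genes whose larger average read count was at least that of the lowest listed gene (5.45 reads), so members under it or without averages did not enter. The median log2 ratio of group averages was also ranked among 10000 random lists drawn from 50 expression bins. This rank too treats genes as independent, and it takes no account of the spread between libraries. Calculations outside R used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

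The genes named in the report follow a rule fixed beforehand: the 12 largest rises and 12 largest falls among called genes with groups apart and a mean of at least 5 TPM, for each list the 3 called members with the largest change or else the 2 most abundant, and 10 known markers of nerve injury (Atf3, Gal, Npy, Sprr1a, Gap43, Csf1, Scn10a, Scn11a, Kcna2 and Oprm1). It gave 118 genes, a few of which are left out of the text. After the data were seen, up to 3 members of each list in the authors' lists and outside the per-library table were added, those with the largest ratio of averages. The rule for pathways took the smallest p, and as the authors' lists held pathway names without p-values, the 10 with most genes were taken for the higher list, and the first 3 for the lower list.

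The test was checked on simulated data with the sham means and fitted spreads of the 1596 genes. It recovered 62% of genes changed by 0.25 on the log2 scale, 96% of those changed by 0.5, 98% of those changed by 1 and 100% of those changed by 2, and unchanged genes made up 5.3% of the calls. A list moved by a planted shift was called by camera, and 0 of 21 lists were called without it. The simulated genes varied independently, so this check cannot show false calls of lists whose genes move together. The list descriptions on the group-average table were tested with planted lists of 20 genes. Planted members were drawn from the authors' higher list, so the Fisher p follows from that overlap and is no check of that test. With 8 planted members the Fisher p was 6.1e-07 and the percentile of the median 96.7, short of the upper limit of 97.5, and with 14 planted members the percentile was 100. A list in which a minority of members changed is therefore not always found by the median.

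The spread between libraries was estimated in genes with at least 100 reads. The median coefficient of variation was 5.66% in sham (1453 genes) and 3.50% in SNI (1483 genes), or 5.90% and 2.76% beyond counting noise. The values beyond counting noise also correct for the low median of a variance estimated from 3 libraries, which is why that of sham is the larger. No pair of libraries held identical values. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 TPM, TMM factors (edgeR 4.0.16), quantile normalization, no trend, the replicate number as a block, leaving out each library, a minimum log2 fold change of 1, the authors' own lists, camera with an estimated correlation, and fry. Leaving out the erythrocyte list and a minimum ratio of 2 between group averages were added after seeing the data.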

Results

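RNA was sequenced from dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of SD rats. In 3 libraries the rats had a spared nerve injury (SNI), in which the tibial and common peroneal branches of the sciatic nerve were tied and cut and the sural branch was left intact. In the other 3 libraries, the sham group, the nerve was exposed and the skin closed. The time from surgery to tissue collection, the spinal level and the side of the ganglia are not given in the sources used here. Expression was deposited as TPM, the share of each transcript among all transcripts of a library. TPM per library was given for 1637 genes and the average TPM of each group for 18696 genes. The authors' average read counts summed to 18.6 M in the sham group and 18.6 M in the SNI group. The depth of each single library is unknown. Values per library are given below as mean ± SD over 3 libraries, and averages from the group-average table have no error. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

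The comparison of SNI with sham asked how the ganglion transcriptome, as one side of a study of transcripts and metabolites in neuropathic pain, differed after nerve injury. With camera at a preset correlation, the lists of erythrocytes (adjusted p = 1.3e-05), injured sensory neurons, complement, class II antigen presentation, macrophages, chemokines and immediate early and dissection stress genes were called higher in SNI, and those of myelinating Schwann cells, potassium channels and transmitter receptors lower. None of these calls was kept with an estimated correlation, where the smallest value was adjusted p = 0.11 with an estimated correlation. Neuropeptide Y (Npy, NCBI Gene ID 24604), a peptide transmitter, stood at 14.4 ± 6.74 TPM in sham and 1452 ± 35.3 TPM in SNI (n = 3 each), a log2 fold change of 6.68 with SE 0.30 (limma adjusted p = 1.3e-07). Galanin (Gal, Gene ID 29141), another peptide transmitter, went from 19.4 ± 2.11 to 533 ± 32.8 TPM, a log2 fold change of 4.71 (SE 0.08, limma adjusted p = 6.9e-10). Of 1596 genes tested with limma, 510 were higher and 466 lower in SNI at a Benjamini-Hochberg adjusted p under 0.05, and 111 and 29 of them had a log2 fold change of at least 1 in size.

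**Figure D1:**
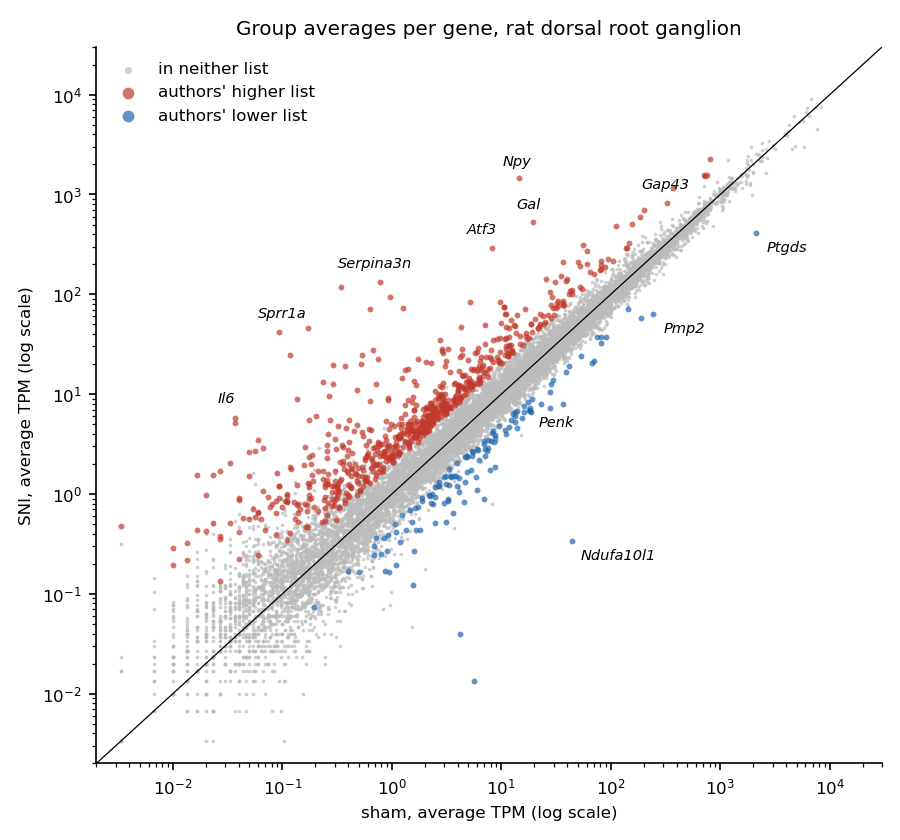
Average TPM of each gene in the sham group (horizontal axis, log scale) and the SNI group (vertical axis, log scale), with the genes of the authors' higher list in red, those of the lower list in blue and the diagonal marking equal averages. Npy lies at 14.4 TPM in sham and 1452 TPM in SNI, and Ptgds at 2127 and 413 TPM.

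Among the other largest rises in the per-library table, Serpina3n, a serine protease inhibitor, rose from 0.773 ± 0.476 to 132 ± 3.22 TPM (log2 fold change 6.26, SE 0.16, limma adjusted p = 3.8e-09). Reg3b, a secreted lectin, rose from 0.967 ± 0.417 to 93.8 ± 1.95 TPM, and Csrp3, a muscle LIM domain protein also known from regenerating axons, from 0.637 ± 0.295 to 71.8 ± 3.91 TPM. The cornified envelope gene Lce1f, the transglutaminase Tgm1, the tight junction gene Cldn4 and the receptor phosphatase Ptprh each lay under 1 TPM on average in sham. In SNI they stood at 24.6, 27.7, 19.6 and 13.25 TPM. The average read count of Lce1f in sham was only 0.67. Alox15, an arachidonate lipoxygenase, rose from 0.520 ± 0.295 to 19.95 ± 1.11 TPM and the chemokine Cxcl14 from 1.39 ± 0.615 to 17.7 ± 1.09 TPM. Rpl30, a ribosomal protein gene with many processed copies in the genome, varied between sham libraries (5.18 ± 6.36 TPM) and stood at 83.3 ± 8.67 TPM in SNI, so its value is uncertain.

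Among the largest falls, Ccl21, a chemokine of lymphatic vessels, fell from 36.2 ± 5.95 to 7.98 ± 0.0666 TPM (log2 fold change −2.04, SE 0.10, limma adjusted p = 2.8e-07). Pmp2, a myelin lipid-binding protein, fell from 241 ± 18.8 to 63.1 ± 4.35 TPM. Pla2g7, a phospholipase that inactivates platelet-activating factor, fell from 81.2 ± 1.83 to 32.6 ± 2.30 TPM, and the opioid peptide precursor Penk from 18.3 ± 1.63 to 7.28 ± 0.782 TPM. The growth factor Igf2, the proline transporter Slc6a20, the monooxygenase Fmo2 and the transcription factor Zbtb16 had log2 fold changes of −1.17, −1.39, −1.22 and −1.19. Ndufa10l1, annotated as like a subunit of respiratory complex I, was at 44.5 ± 2.12 TPM in sham and 0.337 ± 0.307 TPM in SNI. That gene and the uncharacterized loci LOC102553010, LOC100362965 and LOC100363502 (log2 fold changes −1.71, −1.67 and −1.66) resemble copies of other genes or pseudogenes, so reads may have been shared with those copies and their values are uncertain.

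**Figure D2:**
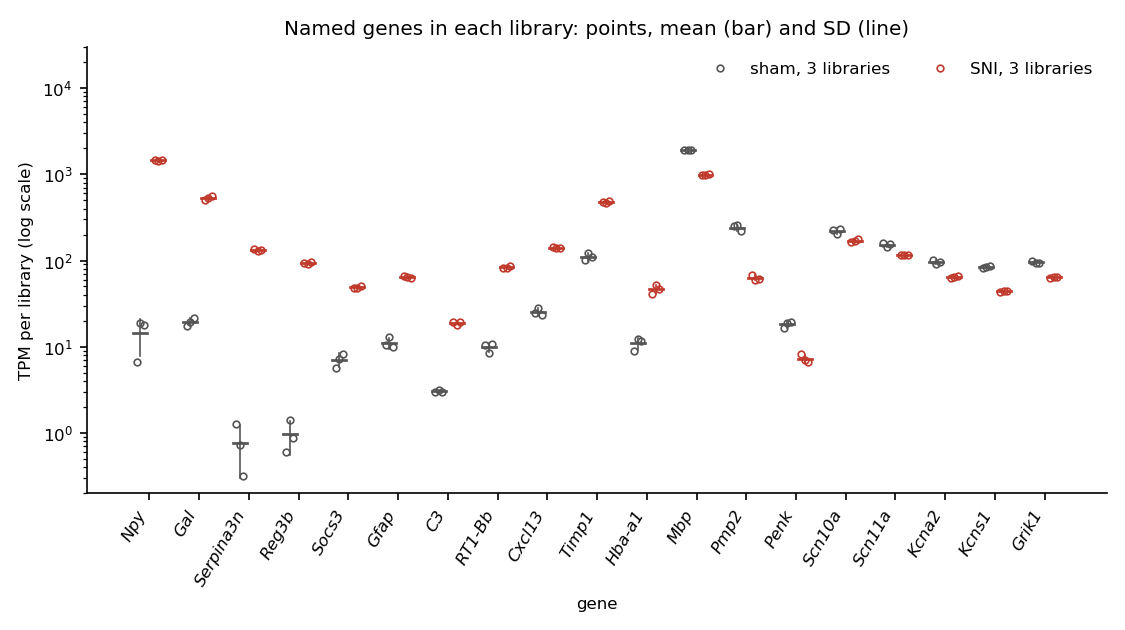
TPM (log scale) of a set of named genes in each of the 6 libraries, sham in grey and SNI in red; points are libraries, short bars the group means and vertical lines the SD. Mbp lies at 1933 TPM in sham and 987 TPM in SNI on average, and in every gene drawn the 3 SNI libraries lie outside the range of the 3 sham libraries.

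Of 35 genes of the injury response of sensory neurons found in the files, 23 were in the authors' higher list and 0 in the lower list (Fisher's exact test, adjusted p = 1.5e-22), and 33 had a higher average in SNI. Fisher's test takes genes as independent units, and the authors' lists came from these same samples. Its p-values, here and below, are therefore no measure of the spread between libraries. The authors' average of Atf3, a transcription factor induced by axon injury, was 8.13 TPM in sham and 288 TPM in SNI. Those of Sprr1a and Gap43, both linked to axon growth, were 0.0933 and 41.8 TPM and 323 and 816 TPM, in that order. The average read count of Sprr1a in sham was only 0.67. Csf1, the growth factor of macrophages, averaged 12.2 and 54.9 TPM, and Arg1, which breaks down arginine, 1.75 and 22.7 TPM. Of 9 members tested with limma, 8 rose, as they did when adjusted over the list alone, among them Socs3, an inhibitor of cytokine signalling (7.07 ± 1.29 to 49.0 ± 1.97 TPM), and the tubulin-binding Stmn4 (34.9 ± 1.83 to 153 ± 0.374 TPM). The injured neuron list was called higher by camera (adjusted p = 0.00011), and the call was lost at adjusted p = 0.11 with an estimated correlation. Macrophage, class II and erythrocyte markers rose with it, at median log2 ratios of 0.98, 1.03 and 1.60. Of the 10 injury-induced neuropeptides, 6 were in the authors' higher list and 1 in the lower list. Averages were given for 9 of them, 5 higher and 4 lower in SNI, and 5 of these 9 were in the higher list (Fisher's exact test, adjusted p = 5.5e-05). Cck averaged 4.40 and 24.8 TPM and Adcyap1, the precursor of PACAP, 60.6 and 274 TPM. Of the 4 peptides tested with limma, 3 rose and Penk fell, over all genes and adjusted over the list alone.

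Of 16 potassium and HCN channel genes tested with limma, 12 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.48 with an estimated correlation). Kcns1, a modifier of voltage-gated potassium channels, fell from 83.8 ± 1.90 to 44.1 ± 0.455 TPM, Kcns3 from 70.5 ± 3.23 to 41.0 ± 1.70 TPM and Kcna2 from 97.1 ± 5.65 to 65.1 ± 1.70 TPM. Kcnip2, a channel-binding protein, was the 1 member of the list among the authors' lower genes, at 18.1 and 6.77 TPM. The member that rose was Kcnn3 (log2 fold change 0.35), named after its value was seen. Of 13 transmitter receptors tested, 9 fell and 4 did not pass, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.0037; adjusted p = 0.48 with an estimated correlation). The kainate receptor Grik1 and the cannabinoid receptor Cnr1 had log2 fold changes of −0.57 and −0.55. In contrast, Gabra5 averaged 6.48 TPM in sham and 23.8 TPM in SNI and Npy2r, a receptor of neuropeptide Y, 6.45 and 13.5 TPM, both in the authors' higher list. The µ-opioid receptor Oprm1 averaged 4.12 and 3.51 TPM and was in neither list, with no test here. TPM are shares of a library, and beside these channel and receptor lists the median log2 ratio was 0.98 for macrophage, 1.03 for class II and 1.60 for erythrocyte genes. A list's median does not give the share of the library that its genes took up. Over all genes with group averages the median log2 ratio was 0.017, so shares did not fall across all genes alike.

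Of 7 sodium and calcium channel genes tested, 4 fell, 1 rose and 2 did not pass, and the list as a whole was not called (camera adjusted p = 0.13). At a mean of at least 5 TPM it was called lower (camera adjusted p = 0.032). Averages were lower in SNI for 20 of its 26 members and higher for 6, with the median at percentile 2.37 of matched random lists. Such percentiles, here and below, take genes as independent and are no measure of the spread between libraries. The nociceptor sodium channels Scn10a (220 ± 15.4 to 170 ± 7.08 TPM) and Scn11a (152 ± 7.68 to 115 ± 0.140 TPM) fell with limma adjusted p of 0.00053 and 9.6e-05, and Scn1a had a log2 fold change of −0.57. Scn3a, a channel subunit of embryonic neurons, rose from 3.29 ± 0.0987 to 5.39 ± 0.318 TPM, a call lost after quantile normalization, where the log2 fold change went from 0.57 to 0.20 (limma adjusted p = 0.0501). Cacna2d1, the calcium channel subunit bound by gabapentin, averaged 40.0 and 142 TPM and was in the authors' higher list. Of 11 nociceptor genes tested, 6 fell, 1 rose and 4 did not pass, with the list not called (camera adjusted p = 0.076). Examples were the itch and pain receptor gene Mrgprd, the peptide Sst and the serotonin receptor Htr3a, with log2 fold changes of −0.55, −0.51 and −0.46. Gfra1, a receptor for the growth factor GDNF, averaged 82.0 and 215 TPM and Nppb 2.43 and 6.36 TPM, both in the authors' higher list, while Th, the enzyme of dopamine synthesis, was in the lower list at 2.71 and 1.21 TPM. Of 6 genes of large-diameter neurons tested, 5 fell and 1 rose, and the list was not called (camera adjusted p = 0.13). Its median log2 ratio of group averages, −0.40, was below all of 10000 random lists matched on expression. Kcnc1 and Esrrg had log2 fold changes of −0.68 and −0.65, and Spp1, osteopontin, rose from 1172 ± 27.1 to 2219 ± 38.7 TPM.

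Of 25 macrophage markers, 13 were in the authors' higher list and 0 in the lower list (Fisher's exact test, adjusted p = 2.3e-11), and 8 of 11 members tested rose, 1 fell and 2 did not pass. Fcgr3a, an antibody receptor, rose from 7.07 ± 1.04 to 31.4 ± 0.832 TPM, the scavenger receptor Msr1 from 2.47 ± 0.230 to 8.80 ± 1.015 TPM and Ms4a7 from 2.68 ± 0.318 to 9.10 ± 0.337 TPM. Itgam, Cx3cr1 and Adgre1, surface proteins of macrophages, averaged 2.24, 5.56 and 4.04 TPM in sham and 8.22, 17.4 and 12.4 TPM in SNI. The perivascular macrophage marker Lyve1 was the member that fell (log2 fold change −0.42), named after its value was seen. All 7 complement genes tested rose, and 8 of 20 were in the authors' higher list (Fisher's exact test, adjusted p = 3.6e-06). C3, the central component, rose from 3.04 ± 0.0929 to 18.9 ± 0.704 TPM, C2 from 22.5 ± 0.501 to 50.8 ± 0.418 TPM and C4b from 9.34 ± 0.872 to 22.1 ± 0.184 TPM, and Cfb, Itgb2 and C1qa averaged 5.64, 4.03 and 81.7 TPM in sham and 17.7, 11.4 and 197 TPM in SNI. All 5 class II genes tested rose, and 10 of 14 were in the authors' higher list (Fisher's exact test, adjusted p = 7.5e-11). RT1-Bb, RT1-Ba and RT1-Da, chains of rat class II molecules, had log2 fold changes of 2.97, 2.09 and 1.83, and RT1-Db1, RT1-DMb and RT1-DOa averaged 29.0, 21.5 and 1.08 TPM in sham and 94.6, 46.1 and 3.34 TPM in SNI. These genes belong to a family of similar sequences that can share reads. The macrophage, complement and class II lists were called higher by camera (adjusted p = 0.0030, 0.00035 and 0.00035), each at adjusted p = 0.11 with an estimated correlation. Erythrocyte markers moved with them: 10 of 11 were in the authors' higher list, all 10 tested rose, and their median log2 ratio was 1.60 (camera adjusted p = 1.3e-05; adjusted p = 0.11 with an estimated correlation).

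Of 40 chemokine and cytokine genes, 17 were in the authors' higher list and 1, Ccl21, in the lower list (Fisher's exact test on the 38 with enough reads, adjusted p = 4.7e-13). Of 10 tested, 9 rose and 1 fell (camera adjusted p = 0.0040; adjusted p = 0.18 with an estimated correlation). The B cell chemoattractant Cxcl13 rose from 25.5 ± 2.56 to 141 ± 2.14 TPM and Cxcl9 from 10.01 ± 1.41 to 51.0 ± 5.49 TPM. Il6 averaged 0.0367 TPM in sham and 5.77 TPM in SNI, and the monocyte chemoattractant Ccl2 27.9 and 106 TPM. The average read count of Il6 in sham was only 0.33. Of 21 lymphocyte markers, 5 were in the authors' higher list (Fisher's exact test on the 18 with enough reads, adjusted p = 0.0022), and all 3 tested rose. Cd3e, a T cell receptor subunit, stood at 0.890 ± 0.226 and 2.33 ± 0.591 TPM and Cd8a at 1.47 ± 0.223 and 2.60 ± 0.150 TPM. Cd3e, Cd8a and the chemokine Ccl5 (log2 fold change 0.28) passed the threshold as deposited and lost it after quantile normalization (limma adjusted p = 0.086, 0.38 and 0.46), and Ccl5 also lost it without sham replicate 1, SNI replicate 1 or SNI replicate 3 (0.062, 0.082 and 0.078). Gzmb, a protease of cytotoxic cells, averaged 0.177 and 5.46 TPM, Cd4 25.2 and 53.1 TPM and Cd8b 0.293 and 1.21 TPM. Gzmb and Cd8b had average read counts of only 2.33 and 3.33 in sham. Cd4 lay far above Cd3e in sham (25.2 against 0.890 TPM), so its rise need not be one of T cells. Of 16 neutrophil and myeloid precursor markers, 5 were in the authors' higher list (Fisher's exact test, adjusted p = 0.0013). Of 3 tested, 2 rose and 1, Mpo, named after its value was seen, did not pass (log2 fold change −0.07). The defensins Defa5 and Np4 rose by log2 fold changes of 0.53 and 0.46, and Retnlg, Lcn2 and Mmp9 averaged 3.10, 22.4 and 1.81 TPM in sham and 8.02, 48.1 and 4.43 TPM in SNI. Beside these lists too, the erythrocyte median log2 ratio was 1.60.

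Of 30 interferon response genes, 21 were tested and 11 rose, 2 fell and 8 did not pass (camera adjusted p = 0.13), and 1, Gbp2 at 26.6 and 62.5 TPM, was in the authors' higher list. Averages were higher in SNI for 23 of the 30, with their median above all matched random lists (percentile 100). Herc6 and the class I gene RT1-A2 rose by log2 fold changes of 0.82 and 0.75, while Ifit1 fell from 19.6 ± 0.555 to 10.6 ± 0.665 TPM. Of 10 mast cell markers, 1 was in each of the authors' lists, and 4 averages were higher and 6 lower in SNI (percentile 0.95). Mcpt1l1, a mast cell protease, fell from 4.08 ± 0.616 to 1.44 ± 0.521 TPM, and Hdc, the enzyme of histamine synthesis, averaged 0.593 and 2.47 TPM. Of 30 cell cycle genes, 28 had a higher average in SNI (percentile 100) and 9 were in the authors' higher list (Fisher's exact test, adjusted p = 1.0e-05), with Mcm5, Prc1 and Ube2c at 2.07, 1.75 and 3.34 TPM in sham and 7.40, 5.08 and 7.83 TPM in SNI. The more abundant Pcna and Aurka were in neither list at 39.9 and 46.4 TPM and 22.9 and 22.5 TPM. Of 5 immediate early and dissection stress genes tested, which tissue handling can also induce, 4 rose (camera adjusted p = 0.021; adjusted p = 0.48 with an estimated correlation). Fos, Junb and Zfp36 had log2 fold changes of 1.82, 1.02 and 0.72. Atf3 belongs to this list and to that of injured neurons. Beside the interferon, cell cycle and immediate early lists, the median log2 ratio was 1.60 for erythrocyte markers and 0.98 for macrophage markers.

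**Figure D3:**
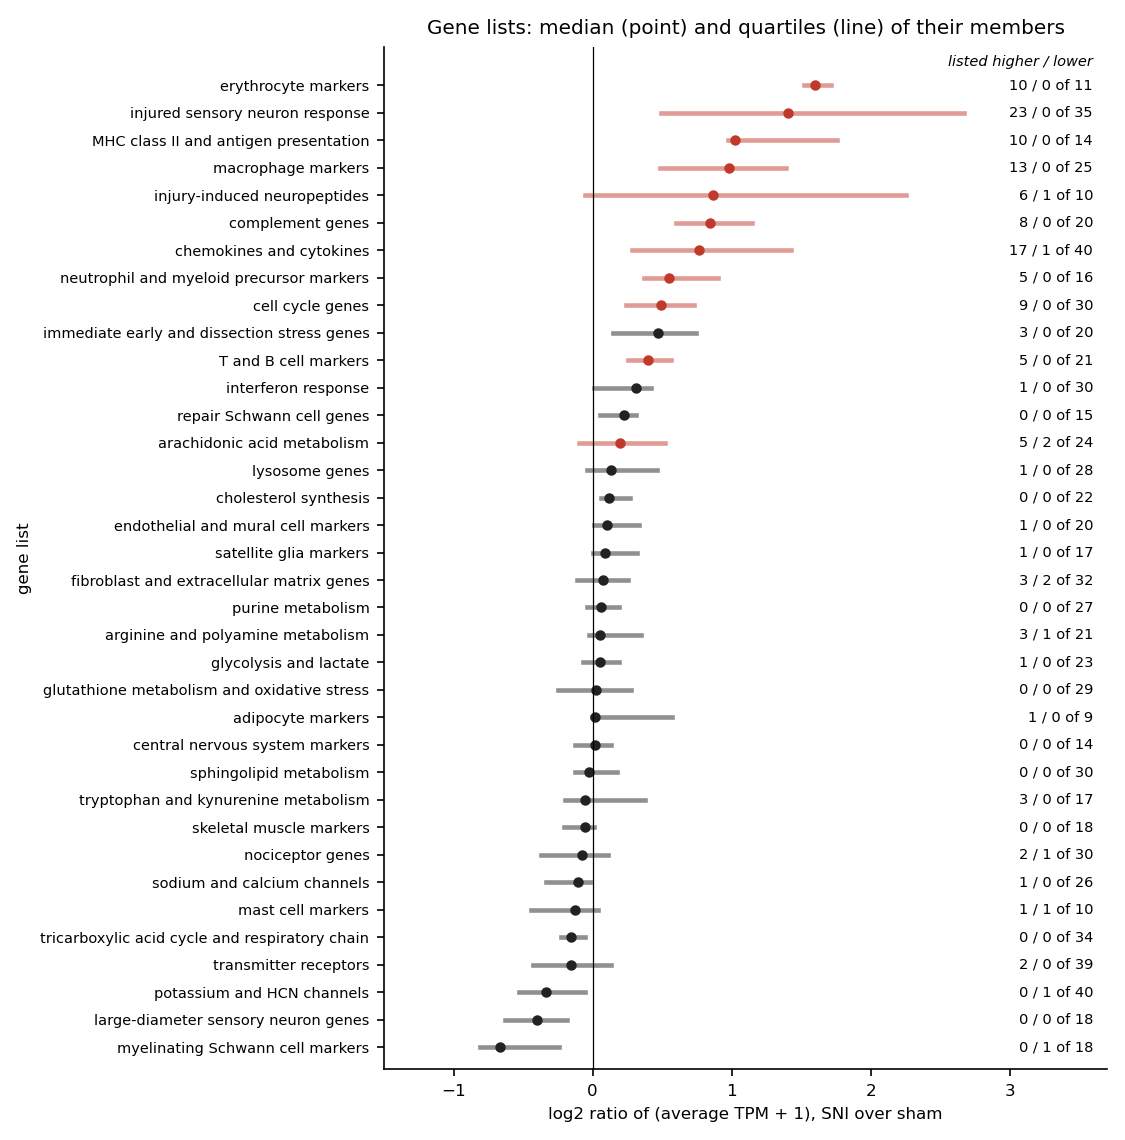
Median (point) and quartiles (line) of the log2 ratio of group averages, SNI over sham, over the members of each of 36 gene lists, with the numbers of members in the authors' higher and lower lists at the right. Lists in red are those with more members in the authors' higher list than other genes (Fisher's exact test), from erythrocyte markers (median 1.60) to arachidonic acid metabolism (0.19), and the lowest median is that of myelinating Schwann cell markers (−0.67).

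Of 9 myelinating Schwann cell genes tested, 8 fell and 1 did not pass, while adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 0.00040; adjusted p = 0.16 with an estimated correlation). As shares of a library, these values stand beside median log2 ratios of 0.98 for macrophage, 1.03 for class II and 1.60 for erythrocyte genes. The median over all genes with group averages was 0.017. Mbp, a myelin protein, fell from 1933 ± 8.97 to 987 ± 13.8 TPM. Of 17 satellite glia markers, the authors' higher list held 1, Gfap, an intermediate filament, which rose from 11.1 ± 1.60 to 64.2 ± 1.40 TPM. Cdh19 rose by a log2 fold change of 0.46, and Apoe fell from 8348 ± 332 to 7526 ± 166 TPM, a call that was lost after quantile normalization (log2 fold change −0.03, limma adjusted p = 0.32). The satellite glia list was not called (camera adjusted p = 0.28). Of 15 genes of repair Schwann cells none was in the authors' lists, 11 averages were higher and 3 lower in SNI (median log2 ratio 0.22, percentile 99.8 of matched random lists), and of 4 tested with limma 2 rose and 2 fell, with log2 fold changes of 0.30 for Megf10, −0.25 for Cadm1 and −0.19 for Egfl8. Of 22 fibroblast and matrix genes tested, 7 rose, 5 fell and 10 did not pass (camera adjusted p = 0.45). Timp1, a metalloproteinase inhibitor, rose from 111 ± 10.8 to 478 ± 11.9 TPM and Thbs2 from 4.62 ± 0.165 to 8.06 ± 0.486 TPM. Dpt fell from 7.58 ± 0.670 to 3.46 ± 0.477 TPM. Mmp3, Postn and Eln averaged 0.05, 1.60 and 17.3 TPM in sham and 2.63, 4.24 and 8.43 TPM in SNI. The average read count of Mmp3 in sham was only 0.67. Of 7 vessel genes tested, 3 rose, 1 fell and 3 did not pass (camera adjusted p = 0.62). Rgs5, Tie1 and Acta2 rose by log2 fold changes of 0.46, 0.34 and 0.33, with the call of Tie1 lost after quantile normalization (limma adjusted p = 0.066), and Des averaged 4.57 and 11.3 TPM.

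Skeletal muscle and central nervous system lists had 0 members in either of the authors' lists and median log2 ratios of −0.05 and 0.01. Pvalb, also made by proprioceptive neurons, averaged 697 and 458 TPM, Acta1 16.0 and 16.5 TPM, the oligodendrocyte gene Mog 4.80 and 5.32 TPM and Hapln2 8.41 and 5.82 TPM. Of 9 adipocyte genes, Cidec alone was in the authors' higher list, at 0.450 and 4.29 TPM, and Cfd rose from 7.65 ± 1.12 to 11.9 ± 2.09 TPM, a call lost after quantile normalization (limma adjusted p = 0.053). A leptomeningeal gene list, drawn up after the lower genes had been seen, had a median log2 ratio of −0.41 over 13 genes, 11 of them lower in SNI, and that median was below all matched random lists (percentile 0). Beside it, Ptgds, the prostaglandin D2 synthase abundant in the meninges, averaged 2127 TPM in sham and 413 TPM in SNI.

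Of 24 genes of arachidonic acid metabolism, 5 were in the authors' higher list and 2 in the lower list (Fisher's exact test for the higher list, adjusted p = 0.0082), and camera did not call the list (adjusted p = 0.40). Besides Alox15 and Ptgds, the prostaglandin E synthase Ptges rose from 3.78 ± 0.820 to 8.75 ± 0.924 TPM and the phospholipase Pla2g2a fell from 7.08 ± 0.497 to 2.41 ± 0.739 TPM, with Ggt5 at 36.3 and 78.8 TPM and Tbxas1 at 2.12 and 5.58 TPM. Tph2, which makes serotonin from tryptophan, rose from 8.43 ± 1.11 to 35.2 ± 0.987 TPM and Aldh2 fell from 104 ± 1.63 to 88.9 ± 1.46 TPM. Maoa and Kmo of the same pathway averaged 33.2 and 0.260 TPM in sham and 76.1 and 1.57 TPM in SNI, and 3 of 17 tryptophan genes were in the higher list (Fisher's exact test, adjusted p = 0.090). Among 21 arginine and polyamine genes 3 were in the higher list and 1 in the lower list (Fisher's exact test for the higher list, adjusted p = 0.13). Gch1, the enzyme of tetrahydrobiopterin synthesis, averaged 1.59 and 13.7 TPM, Ass1 145 and 71.3 TPM, and Gatm, Sat1 and Ddah2 had log2 fold changes of −0.28, −0.20 and 0.15. The call of Ddah2 was lost with TMM factors and without sham replicate 1, sham replicate 3, SNI replicate 1 or SNI replicate 2 (limma adjusted p = 0.077, 0.059, 0.063, 0.093 and 0.072), and that of Sat1 without SNI replicate 3 (0.053).

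The remaining metabolic lists had 0 or 1 member in the authors' lists. Of 11 glutathione and oxidative stress genes tested, 5 rose, 4 fell and 2 did not pass (camera adjusted p = 0.96), with log2 fold changes of 0.80 for the heme oxygenase Hmox1, 0.77 for Gpx2 and −0.67 for Gsta4. Of 10 cholesterol synthesis genes tested, 4 rose and 6 did not pass (camera adjusted p = 0.14), and 20 of 22 averages were higher in SNI (percentile 99.8 of matched random lists), with Lss and Dhcr7 at log2 fold changes of 0.74 and 0.29. Entpd2, which breaks down extracellular nucleotides, and Xdh rose by 0.81 and 0.41 among 4 purine genes tested. Cers4 and Hexa rose by 0.40 and 0.15 in the sphingolipid list, with the call of Hexa lost without SNI replicate 2 or SNI replicate 3 (limma adjusted p = 0.055 and 0.076). Of 7 lysosome genes tested, 3 rose, 2 fell and 2 did not pass (camera adjusted p = 0.76), and 19 of 28 averages were higher in SNI (percentile 99.98), with Cd63, Npc2 and Lamp1 at 0.79, 0.28 and −0.17, and Cd68 averaged 18.5 and 50.3 TPM. Cd68, Ctss and Laptm5 are also macrophage markers, a list with a median log2 ratio of 0.98. In glycolysis, Eno2 had a log2 fold change of −0.11 (limma adjusted p = 0.039) that lost its call without the trend, with the replicate number as a block and without any of the 6 libraries in turn, where the log2 fold change ran from −0.08 to −0.13, and the lactate transporter Slc16a3 averaged 1.90 and 5.38 TPM. Of 34 genes of the tricarboxylic acid cycle and respiratory chain, 30 had a lower average in SNI. Their median log2 ratio of −0.16 was at percentile 0.19 of matched random lists, and Ndufb8 and Ndufa4, the 2 members tested, fell by 0.32 and 0.16. None of 13 mitochondrially encoded genes was found in the files.

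The authors' deposited table of genes higher in SNI named 699 genes, 312 of them with a KEGG pathway, and that of lower genes held 49 with a pathway. In the authors' deposited table of higher genes, the pathways with most genes were cytokine-cytokine receptor interaction (40 genes), metabolic pathways (33), phagosome (30), cell adhesion molecules (29), hematopoietic cell lineage (26), osteoclast differentiation (24), chemokine, Jak-STAT and MAPK signalling (22 each), and complement and coagulation (21). PI3K-Akt signalling tied with the last at 21 genes. In the authors' deposited table of lower genes, metabolic pathways held 14 genes, among them Ptgds, Pla2g7, Ass1 and Th, biosynthesis of secondary metabolites 8 and cytokine-cytokine receptor interaction 5. Metabolic pathways took 28.6% of the annotated lower genes and 10.6% of the annotated higher genes of the authors' deposited tables (two-sided Fisher's exact test, adjusted p = 0.042). Of 42 pathways compared between the lists in this way, 2 passed an adjusted p of 0.05. The lists were chosen by the authors on these same samples, so their counts are not independent evidence of direction.

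In 1064 of the 1596 tested genes (66.7%) the 3 SNI libraries lay outside the range of the 3 sham libraries, against 10% by chance. Of the authors' higher genes, 127 were tested and 125 were higher here, and of the lower genes 32 were tested and 32 were lower. Both come from the same samples, so this agreement is not independent evidence. Higher genes were 52.3% of the calls as deposited, 47.8% with TMM factors and 39.8% after quantile normalization (402 higher and 608 lower), so the balance of directions depends on the scaling. The 1637 genes with values per library were selected by a rule not given in the sources used here and were more abundant than the rest (median sham average 43.5 against 8.72 TPM), so the share of changed genes does not extend to the whole transcriptome. The authors' name for this set speaks of a difference between SNI and sham, though it held 134 of their 699 higher genes. If the rule used that difference, the p-values and the 10% given by chance do not hold within the set.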

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

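The counts of genes higher and lower in SNI (510 and 466) stayed within 1.5 times under other pseudocounts, filters, scalings and without the trend. Without each library in turn they ran from 446 to 522 and from 387 to 477. The labels give no pairing, and with the replicate number as a block they were 498 and 447. Deviations of same-numbered libraries correlated at −0.09, −0.06 and 0.19. A minimum log2 fold change of 1 left 111 and 29, fewer by construction. The authors' lists held 127 and 32 tested genes. Their ratios of average read counts were at least 2.02 or at most 0.515, while the calls had a median absolute log2 fold change of 0.40. A minimum ratio of 2 between group averages, chosen after seeing the data, gave 699 and 160 genes. It ran over the 14944 genes with a larger group average of at least 1 TPM, a different set of genes. Quantile normalization turned the balance to 402 and 608, and the cause was not tested.

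Gene lists called higher and lower (7 and 3) kept their counts without each library in turn, from 7 to 7 and from 3 to 3. With an estimated correlation 0 and 0 were called, with fry 14 and 5. After seeing the data, Fisher's exact test on the authors' lists gave 11 and 0 and the percentile among random lists 16 and 7, which are other tests on other genes. The causes were not tested. Without the erythrocyte list, also chosen afterwards, 6 were called higher. The sodium and calcium channel list was called lower at a mean of at least 5 TPM (camera adjusted p = 0.032), and without a filter the mast cell list, which then had 5 members and could be tested, was called lower (0.042). The named genes were picked mostly as called genes with the largest changes, so their tally does not extend to all calls. Over 107 named genes, 1571 alternatives kept the call, 26 lost it and 0 reversed it. Over the lists, called or not, 335 alternatives kept the result, 10 lost the call and 0 reversed it. Those kept include lists that were never called. All the losses came with an estimated correlation, where every called list lost its call. Another 10 passed newly, all but 1 with fry, which tests a list against no change and not against other genes. DESeq2, voom and size factors were not run, as counts per library are not given in the sources used here, and the pathway threshold was not run for lack of q-values. With no depth per library, counting noise in low genes could not be modelled.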

Other observations

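Outside the rule for named genes, and chosen after their values were seen, several genes of the authors' higher list had large ratios of group averages. Hamp, the iron hormone hepcidin, averaged 0.343 TPM in sham and 118 TPM in SNI, and Stac2, an adaptor of calcium channels, 1.27 and 73.3 TPM. Ucn, the stress peptide urocortin, averaged 0.743 and 22.6 TPM, Ankrd1 0.370 and 19.1 TPM, Crisp3 0.170 and 46.4 TPM and Fcrl2 0.537 and 24.5 TPM. The cytokines Il24 and Tslp averaged 0.290 and 2.73 TPM in sham and 12.6 and 34.8 TPM in SNI. Among the authors' lower genes, the transporters Slc47a1, Slc22a8, Slc22a6 and Slc6a13 averaged 6.04, 3.58, 3.11 and 15.4 TPM in sham and 1.09, 0.643, 0.520 and 5.74 TPM in SNI, Mfap4 27.6 and 7.24 TPM and Cldn11 41.1 and 19.0 TPM.

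The predictions for the Hox genes, non-globin red cell genes, tissue macrophage genes, fibroblast list and splits were written after those values had been seen. Those for platelet genes, S100a8 and S100a9, leptomeningeal genes and on-off genes were written before, though the leptomeningeal list was drawn up after the lower genes were seen. Conditions on read floors and quartiles, and the Hox test without listed genes, were added later and made the labels stricter.

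Hox genes mark position along the body axis, so a difference in ganglion level is 1 technical explanation for Hoxd10, Hoxd11 and Hoxc11 in the authors' higher list and Hoxb8 in the lower list (29.5 and 13.8 TPM). The median log2 ratio of 5 genes of groups 10 to 13 exceeded that of 15 genes of groups 4 to 8 by 1.23 (1.09 and −0.14, exact one-sided permutation over genes p = 0.0023). Without the 4 listed genes, 2 and 14 genes were left and the difference was 0.23 (exact permutation p = 0.1). The SNI ganglia may have come from a more caudal level, but the test cannot tell, and an effect of injury on Hox genes was not tested.

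Higher erythrocyte markers may reflect more blood left in the SNI ganglia. The platelet genes had a median log2 ratio of −0.0043, but their median sham average of 4.67 reads was too low to judge, so the limit written beforehand was unfit. S100a8 and S100a9, abundant in blood neutrophils, had a median of 0.62, between the limits, and cannot tell. Globin transcripts made without red cells are not a fit, as the non-globin red cell genes had a median of 1.54. For the macrophage genes, more blood alone would leave tissue macrophage genes unmoved. Their median was 0.62 over 9 genes (quartiles 0.18 and 0.86), with 8 above 0 and 1 below. That median was on the side of the limit that goes against more blood alone. The limit was written after the values were seen, and the stricter conditions added later put the label at cannot tell. Entry of cells after injury was not tested.

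Less meningeal tissue in the SNI ganglia may underlie the lower Ptgds and transporters. The leptomeningeal genes had a median log2 ratio of −0.41, with 11 of 13 below 0 and Crabp2 the other way at 1.13, and the limits written beforehand put this at cannot tell. The fibroblast and matrix list had a median of 0.0725 (quartiles −0.11 and 0.26), on the side of the limit that goes against fewer fibroblasts of every kind. That limit was written after the values were seen. With 17 members above 0 and 15 below, the median cannot exclude fewer fibroblasts. A biological effect of injury on the meninges was not tested.

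Of 6 genes near 0 in some libraries and clearly above in others, 50% split by group (Cldn4, Lce1f and Ptprh). These were among the largest rises in SNI and would split by group with or without shared RNA. Aph1b, LOC100912618 and LOC103690016 did not split by group, so libraries within a group differed in them. So few genes cannot tell whether the libraries of a group share RNA. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 976 genes past the threshold and the highest other 0, but 10 splits are too few for a test.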
